A study of Mus musculus with 3 samples.

How the data were processed

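Genomic DNA of 3 thymic lymphomas was measured on 3 custom Agilent arrays by comparative genomic hybridisation, a method that sets the DNA amount of a tumour against that of normal tissue at many positions. Per the labels, the mice were female B6C3F1 animals, the first-generation offspring of a cross between the strains C57BL/6 and C3H, given whole-body X-rays of 2.0 Gy at 0.7 Gy per min once a week in 4 exposures from the age of 4 weeks. On each array the red dye (Cy5) carried lymphoma DNA and the green dye (Cy3) carried ear DNA of the same mouse, with 0.4 µg of DNA labelled, per the labels' protocols. The dyes were not swapped on any array, so a dye effect tied to a probe stays in every ratio. All 3 arrays lay on 1 slide, so there was no slide batch to test.

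Spot intensity values were produced with Agilent Feature Extraction 9.5.1, per the file headers and the submitters' processing notes. Per the file headers, the processed intensity of each dye had been background-subtracted with a spatial trend removed and then scaled by a linear factor per dye. The deposited log10 ratio of a spot was the ratio of these processed red and green signals, except at 1 spot of TL8 where the deposited log10 ratio differed from the signals by more than 0.001. The deposited p-value of each spot's log ratio and its error came from the error model of Feature Extraction, per the file headers, and were not used here. The authors' value table held log2 ratios of tumour over ear for 13662 probes, in the same direction as the scanner files. Outside the 222 repeated probes, which this check left out, each column equalled the Feature Extraction log ratio plus a constant. The constant was -0.08 for TL11, -0.16 for TL8 and -0.17 for TL20 on the log2 scale, and how it was set stays unknown. The medians of the table were -0.04 for TL11, -0.06 for TL8 and -0.13 for TL20. The genome build of the probe coordinates was not given in the sources used here, and coordinates are printed as the files give them.

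Each array held 15448 spots, of which 1564 were control spots and were left out. The other 13884 spots carried 13662 distinct probes, 222 of them repeated. No spot was saturated in either dye. Outlier-flagged spots were left out, which removed 1 spot of TL20. The log2 ratio of the processed red over green signals was averaged over the spots of a probe and centred on the median of all probes of the array. The medians before centring were 0.05 for TL11, 0.10 for TL8 and 0.04 for TL20. The number of arrays limits the precision. The noise between neighbouring probes, as an SD on the log2 scale, was 0.13 for TL11, 0.14 for TL8 and 0.12 for TL20. The median ear signal was 6.92 times the local background for TL11, 8.08 times for TL8 and 8.34 times for TL20, and the median tumour signal was 9.42, 9.65 and 11.3 times the local background in the same order.

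Circular binary segmentation was run on each chromosome of each array with alpha 0.01, 1000 permutations and at least 3 probes per segment. Neighbouring segments were merged where their means differed by less than 1 SD of the probe noise. A segment was called lost at a median log2 ratio of -0.25 or lower, gained at 0.25 or higher and deeply lost at -1.0 or lower. These calls describe 1 array each and have no replicate check, and the SD given for a segment is that between its probes. The median per chromosome window was compared with 0 by an exact sign-flip permutation test, two-sided, whose smallest p for 3 values is 0.25. Probes that differed from 0 over the tumours were sought with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment at 0.05), with the 3 tumours as replicates. The other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

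The segmentation was tested on simulated arrays with 1200 probes and the measured noise. It called 20 of 20 planted segments of 13 probes at -3.0, 19 of 20 of 60 probes at -0.7, 18 of 20 of 60 probes at -0.4, 20 of 20 of 39 probes at 0.55 and 20 of 20 of 15 probes at 0.55, with both edges within 2 probes. It made a call in 0 of 20 arrays without a planted change. The simulated arrays held probe noise alone, while the real tumours shared a profile along the chromosomes, with a Pearson r between tumours of 0.93 to 0.95 over 47 bins of 250 kb on chromosome 11 and of 0.74 to 0.89 over 48 bins on chromosome 16. The 0 of 20 therefore says nothing on weak gained calls such as those of TL11. The limma step was tested on 13662 simulated probes in 3 arrays and recovered 100% of probes planted at -1, 100% at -0.6, 100% at 0.6 and 76% at 0.3, and called 0.0817% of the probes left at 0. That simulation held probe noise and no differences between tumours.

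The files pair no probe with a gene, and the gene table at hand is of the assembly GRCm38.p6. In that table, the positions of the genes Notch1, Cdkn2a and Cdkn2b fell outside the probe windows, and those of Pten, Ikzf1 and Bcl11b fell inside. The probe coordinates may therefore be of another assembly, and the table was used for names, chromosomes, lengths and the order of genes alone. All 145 distinct genes of the lists fixed before the data were examined matched that table, and 74 lie on a chromosome with a probe window. None could be placed in a segment, so the planned counts per gene list and the planned medians of antigen receptor loci were not computed. The planned median over the probes within Pten was replaced by the whole chromosome 19 window and its segments. The rule for naming, fixed before the data were examined, took Pten and its neighbours, the 5 lost and the 5 gained segments of each tumour ranked highest by absolute median times the square root of the probe number, the genes of the lists in called segments, the 10 limma results of smallest adjusted p and the genes in deeply lost segments. Without gene names, segments and probes took the place of the genes. The repeats with other settings were normexp background correction with offset 50 on median spot signals, the authors' value table, no centring, centring on the mode or outside chromosome 19, no outlier filter, dim probes left out, call thresholds of 0.15 and 0.4, alpha 0.001, no merging, at least 5 probes per called segment, each tumour left out in turn, an intensity trend with robust fitting in limma, the mean or 1 Mb windows for chromosome medians, and removal of the trend on probe length. The last was chosen after seeing the data.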

Results

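Copy number was measured in 3 thymic lymphomas that arose in irradiated mice, named TL11 (replicate 1), TL8 (replicate 2) and TL20 (replicate 3), each against ear DNA of the same animal. The array did not cover the genome. Its 13662 probes lay in 6 windows, on chromosomes 2, 4, 11, 12, 16 and 19. The chromosome 2 window spanned 26266608 to 26409525 with 531 probes, and the chromosome 4 window spanned 88735664 to 89189108 with 1231 probes. Chromosome 11 was covered from 4290243 to 23139431 with 5230 probes, chromosome 12 from 91689792 to 113904198 with 2147 probes, and chromosome 16 from 3474500 to 18126918 with 3013 probes. The chromosome 19 window spanned 32569094 to 33000696 with 1510 probes at a median spacing of 236 bp. Genes are named below only by the chromosome that carries them, because the genome build of the coordinates was not given in the sources used here and the position of each gene among the probes was not determined. All values are log2 ratios of tumour over ear, centred on the array median, and each tumour was measured on 1 array.

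**Figure D1:**
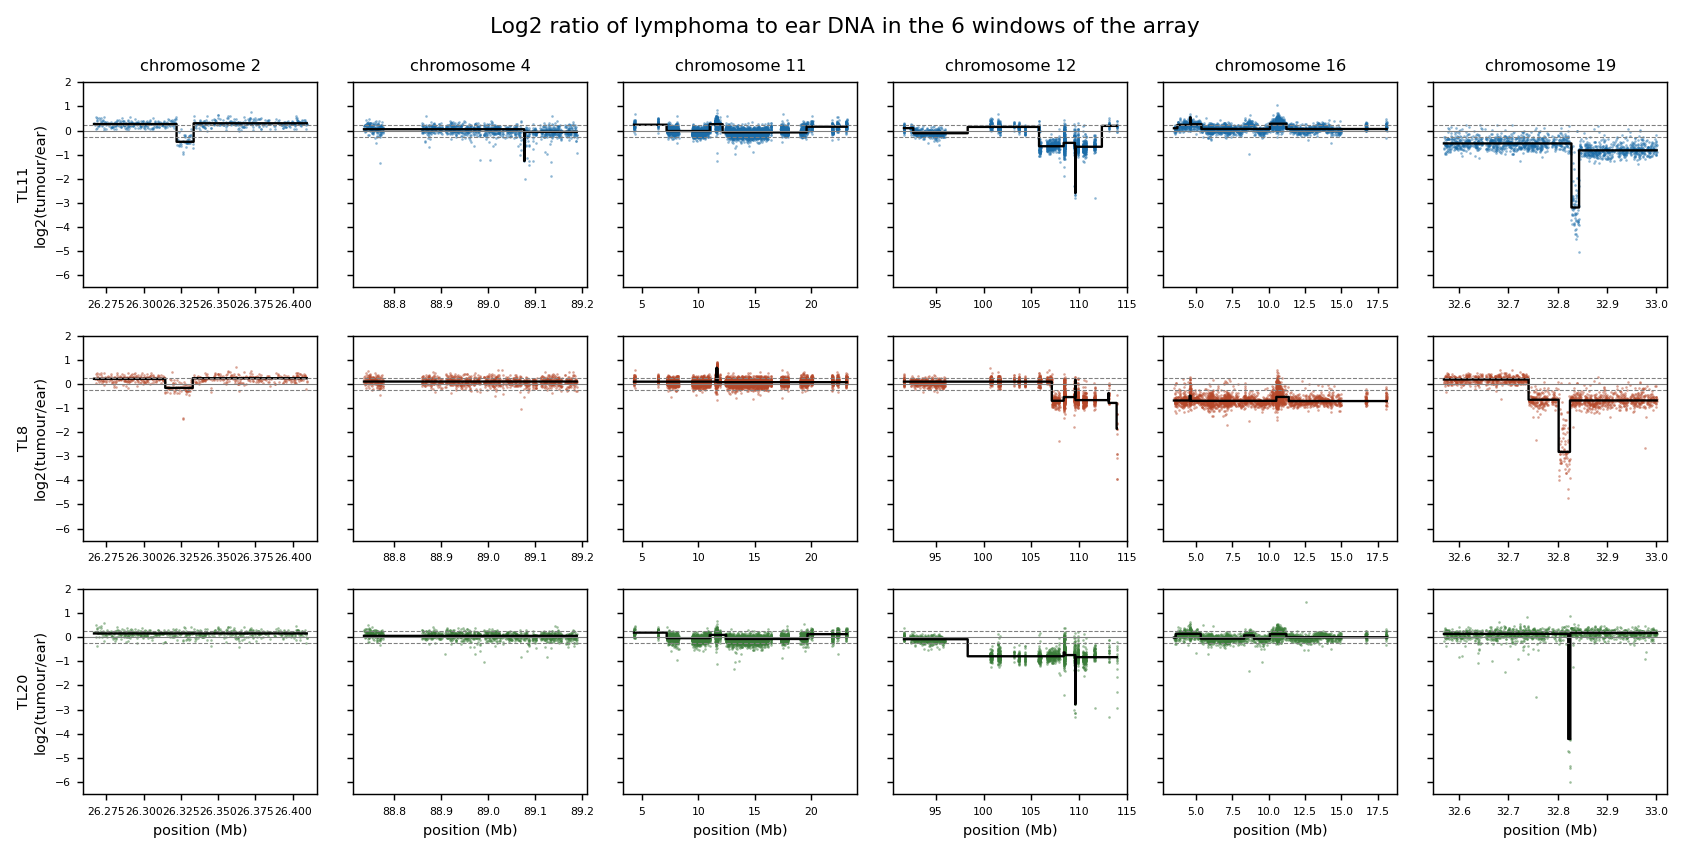
Log2 ratio of tumour over ear (vertical axis, no unit) against position in Mb (horizontal axis) for the 3 tumours (rows) in the 6 windows (columns). Points are probes, black lines are segment medians drawn across stretches without probes, and dashed lines mark -0.25 and 0.25. Deep segments stand out on chromosome 19 in each tumour, and chromosome 16 lies low in TL8 alone.

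The first question, set by the title of the series, concerned inactivation of Pten in the tumours. Pten, a lipid phosphatase that opposes PI3K signalling and a tumour suppressor in T cells, lies on chromosome 19. Each of the 3 tumours carried 1 deep segment inside the chromosome 19 window, and the state of the surrounding DNA differed between them. TL11 had lost the whole window, with a deep segment inside it. TL8 had lost the distal part of the window, with a deep segment inside that loss. TL20 had a short deep segment between flanks that were not lost.

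In TL11 the segment from 32569094 to 32827626 had a median of -0.53 ± 0.22 (SD between 888 probes). The deep segment from 32827812 to 32843148, 15.3 kb long, had a median of -3.19 ± 0.98 (SD between 71 probes). The segment from 32843400 to 33000696 lay at -0.82 ± 0.23 (SD between 551 probes). Of the 71 probes in the deep segment, 66 lay below -1, the value that loss of 1 of 2 copies gives in a pure sample.

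In TL8 the first 603 probes, from 32569094 to 32740590, had a median of 0.18 ± 0.13 (SD) and were not lost. The 197 probes from 32741070 to 32801708 lay at -0.66 ± 0.26 (SD). A deep segment of 22.6 kb followed, from 32801899 to 32824532, at -2.82 ± 0.98 (SD between 75 probes), with 70 of the 75 probes below -1. The remaining 635 probes, from 32825021 to 33000696, lay at -0.69 ± 0.24 (SD).

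In TL20 the deep segment was 4.02 kb long, from 32821444 to 32825463, with a median of -4.22 ± 1.86 (SD between 13 probes). Of these 13 probes, 11 lay below -1. The flanks had medians of 0.14 ± 0.21 (SD between 865 probes) and 0.17 ± 0.15 (SD between 632 probes). No run of the same number of neighbouring probes on the other chromosomes was as low as the deep segment of chromosome 19 in any tumour, with 0% of 11802 runs for TL11, 0% of 11782 for TL8 and 0% of 12091 for TL20.

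The deep segments of TL8 and TL20 overlapped by 3.09 kb, from 32821444 to 32824532, a stretch with 10 probes. The deep segment of TL11 did not overlap the others. It began 3.28 kb after the end of the segment of TL8 and 2.35 kb after that of TL20. Together the deep segments spanned 41.2 kb, from 32801899 to 32843148, which was 9.56% of the window. In GRCm38.p6, Pten is 68.6 kb long and its nearest protein-coding neighbours are Minpp1, Papss2 and Atad1 on one side and Lipo4 and Lipo3 on the other. Which of these genes the deep segments touch was not determined, because the probe coordinates may be of another assembly than GRCm38.p6. The medians of the whole window were -0.64 ± 0.61 for TL11, -0.51 ± 0.70 for TL8 and 0.15 ± 0.44 for TL20 (SD between 1510 probes). With normexp signals the deep segments were shallower, at -1.77 in TL11, -1.77 in TL8 and -2.72 in TL20, all below -1.0.

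**Figure D2:**
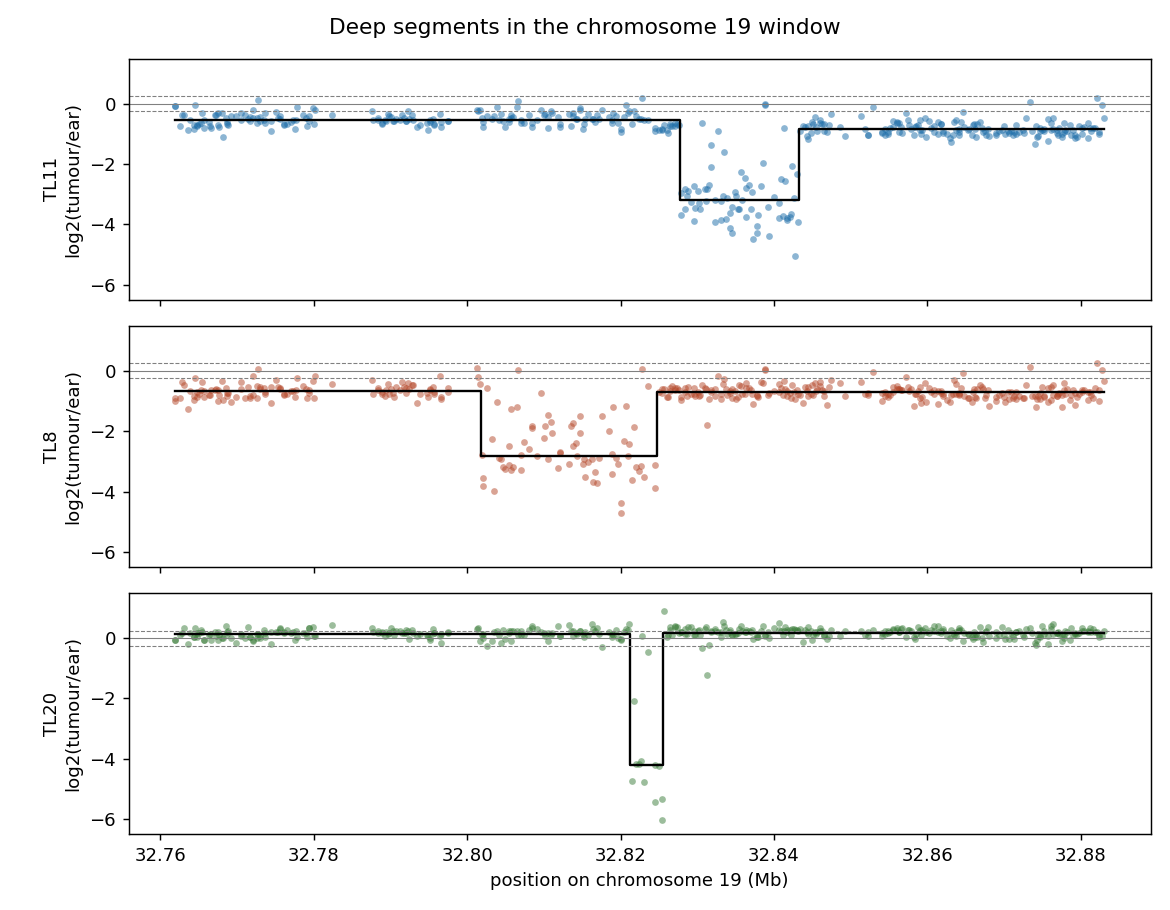
Log2 ratio of tumour over ear (vertical axis, no unit) against position on chromosome 19 in Mb (horizontal axis) around the deep segments, 1 panel per tumour. Points are probes, black lines are segment medians and dashed lines mark -0.25 and 0.25. The deep segments of TL8 (-2.82) and TL20 (-4.22) overlap, and that of TL11 (-3.19) lies beyond them.

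The second question was which other windows had changed copy number in each tumour. Chromosome 12, which carries Bcl11b, a transcription factor needed for T cell development, was partly lost in all 3 tumours. Chromosome 16 was lost over its whole window in TL8 alone. TL11 carried a short loss on chromosome 2, which carries the receptor gene Notch1, and TL8 carried short gains on chromosome 11, which carries Ikzf1, a transcription factor of lymphoid cells. The chromosome 4 window, on the chromosome of the cell cycle inhibitors Cdkn2a and Cdkn2b, held 1 called segment in the 3 tumours, one of 3 probes in TL11 that was not called in every setting.

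TL11 had 10 lost segments with 2844 probes (20.8% of all probes), 6 gained segments with 2454 probes (18.0%) and 3 deep segments. TL8 had 14 lost segments with 5033 probes (36.8%), 3 gained segments with 65 probes (0.476%) and 2 deep segments. TL20 had 6 lost segments with 1708 probes (12.5%), 0 gained segments and 2 deep segments. The gained probes of TL11 depended on the processing, with 263 under centring outside chromosome 19 and 5 once the trend on probe length was removed, a setting chosen after seeing the data.

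On chromosome 12 the loss began at a different position in each tumour. In TL11 it ran from 105794820 to 111660716, led by a segment of 411 probes at -0.65 ± 0.20 (SD) up to 108362988 and one of 354 probes at -0.67 ± 0.26 (SD) from 109591483. No probe lay in the next 1388063 bp, and the 34 probes from 113048779 on were back at 0.19 ± 0.14 (SD) in TL11. In TL8 it ran from 107130884 to the end of the window, with a first segment of 209 probes at -0.70 ± 0.23 (SD). In TL20 it ran from 100697943 to the end, with a first segment of 782 probes at -0.79 ± 0.20 (SD) and a last one of 388 probes from 109591483 at -0.83 ± 0.33 (SD). No probe lay in the 4705760 bp before 100697943, so the loss in TL20 may have begun anywhere in that gap. TL20 was further lost from 108363228 to 108476382 at -0.63 ± 0.29 (SD between 414 probes) and from 108476613 to 109585070 at -0.74 ± 0.36 (SD between 104 probes). The first of these was densely tiled, with 414 probes in 113 kb against a median spacing of 1653 bp in the window. TL11 and TL8 also stepped up from 108363228 on, to -0.51 and -0.55. With the length trend removed the stretch lay at -0.71 in TL20. The cause of this shared step was not tested. Of the probes lost in all 3 tumours, 1079 lay on chromosome 12 within 4.53 Mb, from 107130884 to 111660716, with medians of -0.59 in TL11, -0.63 in TL8 and -0.73 in TL20. The other 13 were the probes of the deep segment of TL20 on chromosome 19.

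Inside the shared loss of chromosome 12, 7 probes from 109585433 to 109590955 formed a deep segment in TL11, at -2.59 ± 0.93 (SD), and in TL20, at -2.78 ± 1.03 (SD). In TL8 the same 7 probes had a median of 0.18 ± 0.07 (SD), although the DNA on both sides was lost. With normexp signals the 7 probes lay at -1.59 in TL11 and -1.91 in TL20. A deep segment of TL8 at the end of the window, from 113893070 to 113904198, had a median of -1.86 ± 1.09 (SD between 14 probes). The same probes lay at -0.91 ± 0.73 (SD) in TL20 and at 0.16 ± 0.14 (SD) in TL11.

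**Figure D3:**
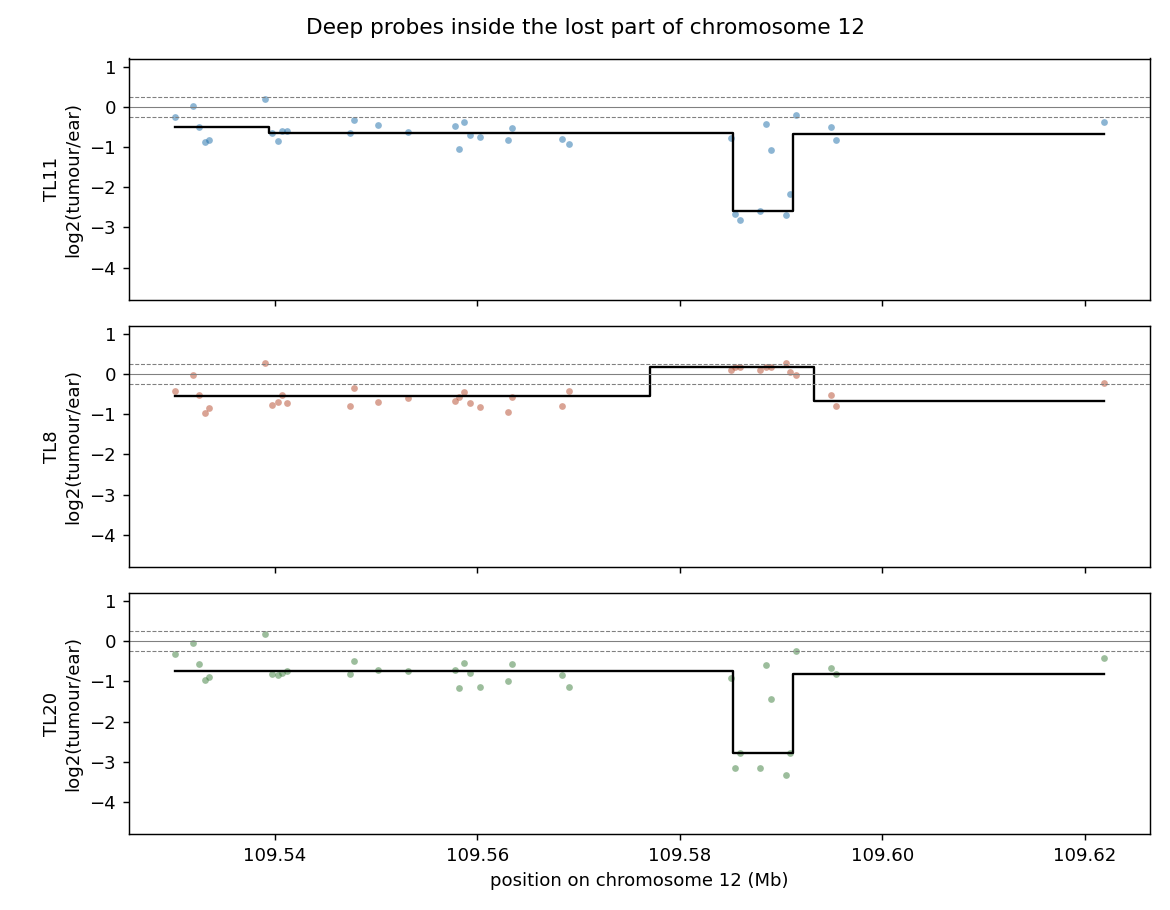
Log2 ratio of tumour over ear (vertical axis, no unit) against position on chromosome 12 in Mb (horizontal axis), 1 panel per tumour. Points are probes, black lines are segment medians and dashed lines mark -0.25 and 0.25. The 7 probes near the centre lie at medians of -2.59 in TL11 and -2.78 in TL20 and at 0.18 in TL8.

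On chromosome 16, TL8 was lost in 5 segments that covered all 3013 probes. The segment from 4627116 to 10522971 had a median of -0.70 ± 0.20 (SD between 1232 probes), that from 10523012 to 11358361 of -0.54 ± 0.28 (SD between 854 probes) and that from 11406613 to 18126918 of -0.71 ± 0.17 (SD between 541 probes). Neither TL11 nor TL20 had a lost segment there. TL11 had gained segments from 10088257 to 11216274 at 0.28 ± 0.13 (SD between 1003 probes) and from 4601241 to 5359440 at 0.26 ± 0.12 (SD between 155 probes), just above the threshold of 0.25. A short one, from 4599792 to 4600696, had 0.55 ± 0.09 (SD between 4 probes) in TL11. Its probes lay at 0.39 in TL20 and -0.38 in TL8. The neighbouring segments on either side lay at 0.24 and 0.26 in TL11. The probes of these neighbours lay at 0.14 and 0.12 in TL20 and at -0.64 and -0.61 in TL8. The 4 probes thus stood above both neighbours in all 3 tumours. The segments from 10088257 and from 4601241 lay under 0.25 with normexp signals, in the authors' table and with centring outside chromosome 19. With the length trend removed they lay at 0.21 and 0.24. The segment from 4601241 also lay under 0.25 with centring on the mode, at 0.247.

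On chromosome 2, TL11 had a lost segment of 11.1 kb from 26322173 to 26333309 at -0.47 ± 0.22 (SD between 41 probes). Its flanks lay at 0.27 ± 0.12 (SD between 231 probes) and 0.30 ± 0.13 (SD between 259 probes), so that the segment lay below them by a shift of -0.75. The flanks were called gained, and their medians were 0.07 and 0.12 once the trend on probe length was removed. The first flank also lay under 0.25 with normexp signals (0.24), in the authors' table (0.23) and with centring outside chromosome 19 (0.23). TL8 had a segment of 18.2 kb from 26314569 to 26332795 at -0.17 ± 0.28 (SD between 66 probes), a shift of -0.39 from its flanks, which did not reach the threshold for a loss. It passed that threshold at -0.26 when the array was centred on the mode and also at -0.26 with the length trend removed. TL20 formed 1 segment over the window at 0.16 ± 0.13 (SD between 531 probes).

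**Figure D4:**
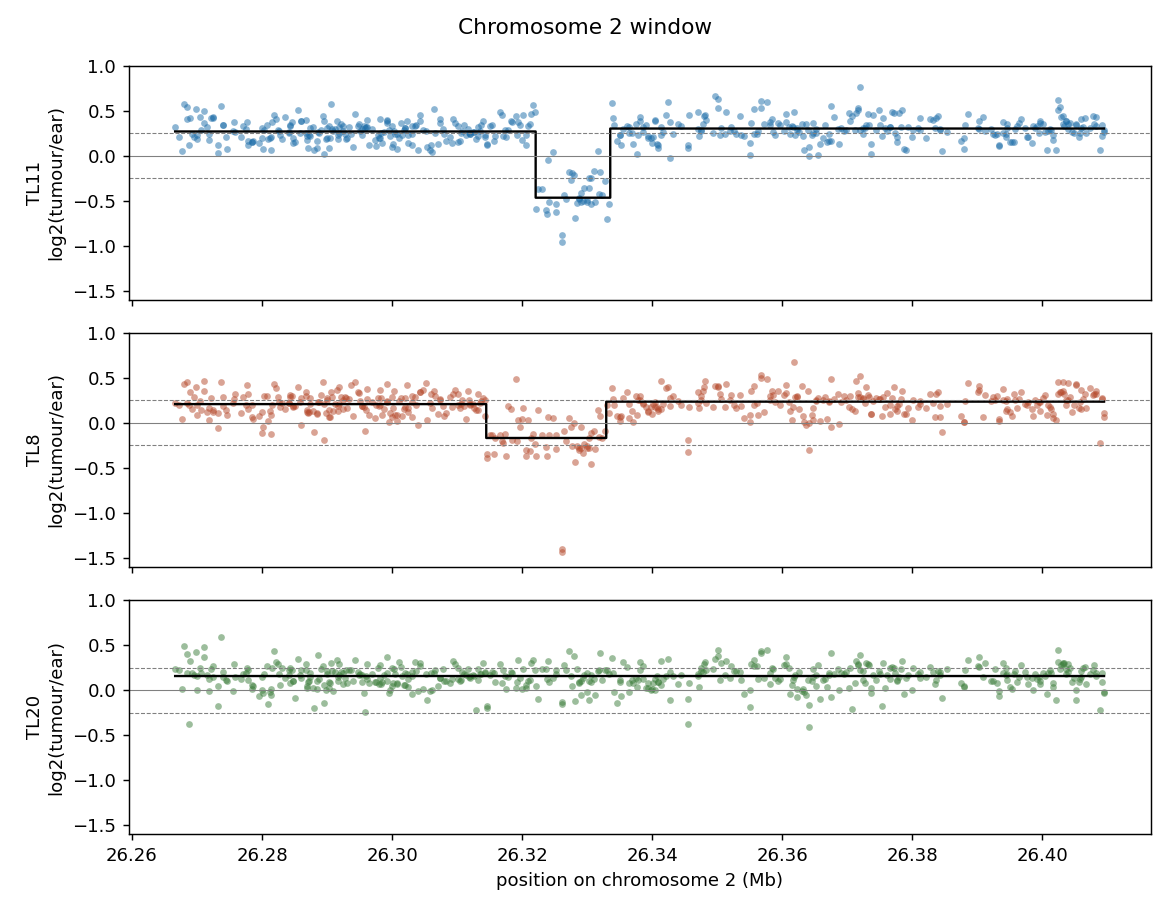
Log2 ratio of tumour over ear (vertical axis, no unit) against position on chromosome 2 in Mb (horizontal axis), 1 panel per tumour. Points are probes, black lines are segment medians and dashed lines mark -0.25 and 0.25. The segment of TL11 lies at -0.47 and that of TL8 at -0.17, and TL20 shows no step.

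On chromosome 11, TL8 had 3 gained segments within a short stretch. The first, of 9.36 kb from 11614555 to 11623919, had a median of 0.67 ± 0.17 (SD between 39 probes). The second, from 11665734 to 11667590, had 0.41 ± 0.08 (SD between 9 probes), and the third, from 11667608 to 11670828, had 0.65 ± 0.12 (SD between 17 probes). The 185 probes between the first and the second lay at 0.13 ± 0.14 (SD). At the 39 probes of the first, the medians were 0.29 ± 0.13 (SD) in TL11 and 0.17 ± 0.15 (SD) in TL20, and at the 17 probes of the third they were 0.28 ± 0.15 (SD) and 0.15 ± 0.13 (SD). At the 9 probes of the second, TL11 lay at 0.35 ± 0.11 (SD) and TL20 at 0.25 ± 0.14 (SD), so that TL8 exceeded TL11 by less than the spread between probes there. The second segment of TL8 moved to 0.51 without centring, 0.32 with centring on the mode and 0.31 with the length trend removed. TL11 had a broader gained segment from 11006705 to 11916757 at 0.27 ± 0.15 (SD between 802 probes). It lay under 0.25 with normexp signals (0.22), in the authors' table (0.23), with centring outside chromosome 19 (0.23) and with the length trend removed (0.24). The same probes lay at 0.15 in TL8 and 0.10 in TL20, in a densely tiled part that was raised in all 3 tumours. On chromosome 4, the deep segment of TL11 from 89077148 to 89077806 had a median of -1.26 ± 0.51 (SD between 3 probes). It was not deep with normexp signals, at -0.78, and it was not called at a segmentation alpha of 0.001 or with at least 5 probes per called segment.

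**Figure D5:**
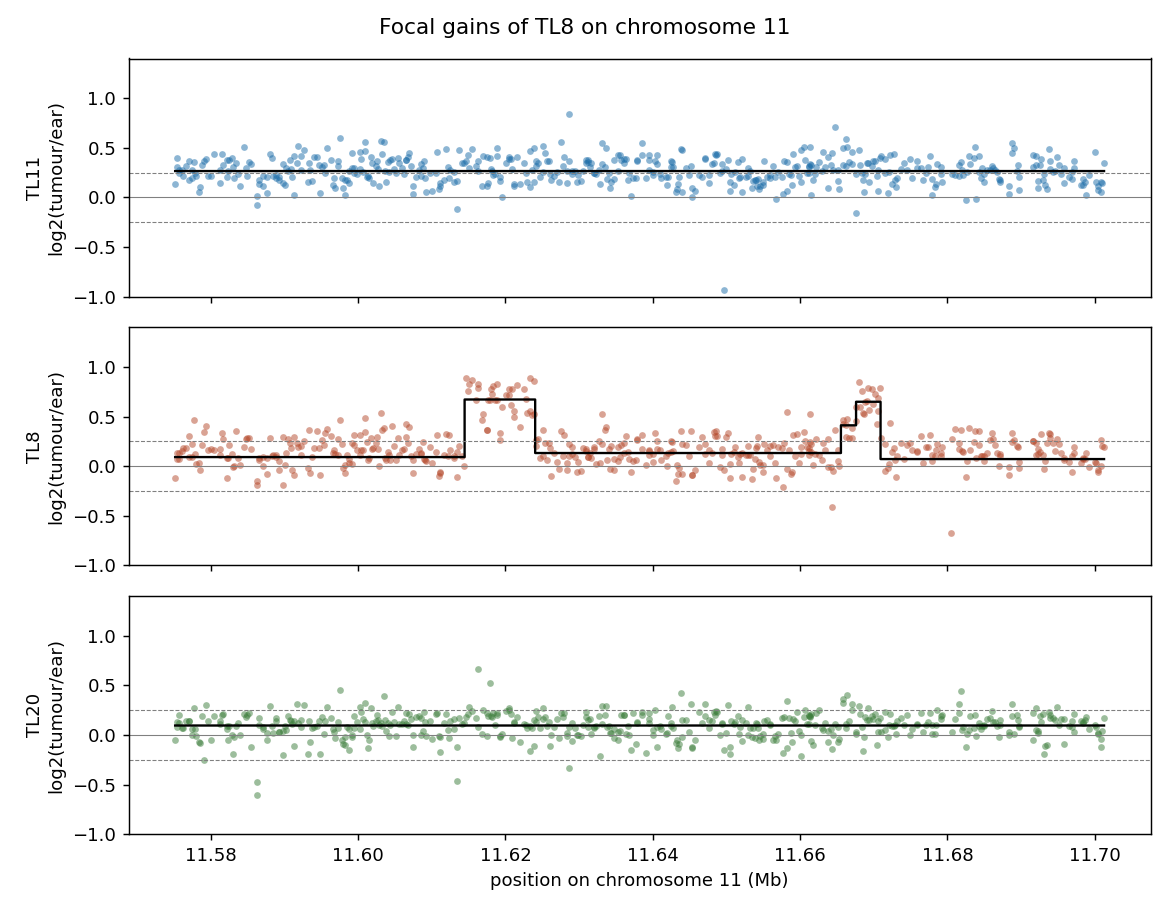
Log2 ratio of tumour over ear (vertical axis, no unit) against position on chromosome 11 in Mb (horizontal axis), 1 panel per tumour. Points are probes, black lines are segment medians and dashed lines mark -0.25 and 0.25. TL8 steps up to 0.67, 0.41 and 0.65 in 3 short segments. At the second, TL11 and TL20 also lie raised, at 0.35 and 0.25.

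The third question was which windows and probes moved the same way over the 3 tumours. Chromosome 12 had a mean of the window medians of -0.40 ± 0.29 (SD, n = 3 tumours) and was below 0 in 3 of 3 tumours (exact sign-flip test, two-sided, p = 0.25, the smallest p that 3 tumours allow, adjusted p = 0.5). Chromosome 19 had a mean of -0.33 ± 0.43 (SD, n = 3, exact p = 0.5, adjusted p = 0.75) and was below 0 in TL11 and TL8. Chromosome 16 had -0.15 ± 0.45 (SD, n = 3, exact p = 1, adjusted p = 1). Chromosome 2 had 0.21 ± 0.06 (SD, n = 3, exact p = 0.25, adjusted p = 0.5), chromosome 4 had 0.06 ± 0.04 (SD, n = 3, exact p = 0.25, adjusted p = 0.5) and chromosome 11 had 0.02 ± 0.06 (SD, n = 3, exact p = 1, adjusted p = 1). Several means changed when 1 tumour was left out or with the processing. That of chromosome 2 was 0.06 with the length trend removed, 0.14 in the authors' value table and 0.27 without centring. That of chromosome 12 was -0.25 without TL20 and -0.27 as the median over 1 Mb windows, that of chromosome 19 was -0.18 without TL11 and -0.57 without TL20, and that of chromosome 16 was -0.31 without TL11, -0.25 without TL20 and 0.11 without TL8. Chromosome 16 further went to -0.09 without centring and to -0.22 in the authors' value table. The mean of chromosome 4 was 0.04 without TL8, 0.12 without centring and 0.02 with centring on the mode, and turned to -0.02 in the authors' value table. That of chromosome 11 turned to -0.06 in the same table, -0.02 with centring on the mode and -0.01 without TL8, and was 0.08 without centring, 0.03 without TL11 and 0.04 without TL20.

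By limma, 686 of 13661 probes were lower in tumour than in ear and 22 were higher after Benjamini-Hochberg adjustment. Of the lower probes, 680 lay on chromosome 12 between 107130884 and 111660716, and 681 of the 686 were among the probes lost in all 3 tumours. The median of their mean log2 ratios on chromosome 12 was -0.72, with a median SE of 0.06 and a smallest adjusted p of 0.0325 by limma, and all 680 were below 0 in 3 of 3 tumours. Of the higher probes, 10 lay on chromosome 2 and 7 on chromosome 11. The counts of lower and of higher probes fell to 0 when any 1 of the tumours was left out, TL11, TL8 or TL20, and when the arrays were not centred. Without TL11, 1006 probes were lower at an unadjusted p under 0.05 by limma, without TL8 1668 and without TL20 1655, against 1347 with all 3. The higher probes at that unadjusted p by limma numbered 308 without TL11, 1242 without TL8 and 469 without TL20, against 1241 with all 3.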

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

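Removal of the trend on probe length was chosen after seeing the data. Among the values that answer a comparison, 196 stayed within their spread or within 1.5 times and 32 moved, and of the named segments 194 stayed and 6 moved. The moved segments were both flanks on chromosome 2 in TL11 with the length trend removed, the 7 probes of chromosome 12 in TL11 with normexp signals (-1.59) and, under 3 settings, the chromosome 11 segment of TL8 from 11665734. No called value changed sign under the settings run, and the means of chromosomes 4, 11 and 16, which were not called, did. Lost probes per tumour stayed within 1.5 times under each of them.

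Gained probes of TL11 (2454) were 259 with normexp signals, 263 in the authors' value table, 263 with centring outside chromosome 19, 5 with the length trend removed, 3712 at a threshold of 0.15 and 4 at 0.4. Those of TL8 (65) were 1142 without centring and 1142 at 0.15, and those of TL20 (0) were 1280 at 0.15. With normexp signals, whose offset compresses low signals, the deep segments of chromosome 19 were -1.77 in TL11, -1.77 in TL8 and, within its spread between probes, -2.72 in TL20. The mean of chromosome 2 was 0.135 in the authors' value table, 0.271 without centring and 0.0636 with the length trend removed. That of chromosome 4 was -0.0185 in the table, 0.118 without centring and 0.0175 with centring on the mode, and that of chromosome 11 was -0.0564 in the table and 0.0799 without centring. Lower limma probes (686) were 0 without centring and from 0 to 0 with a tumour left out. Higher probes (22) were 8 with normexp signals, 0 in the table, 0 without centring, 11 with centring on the mode, 13 with the length trend removed, 79 with the intensity trend and robust fitting, and from 0 to 0 with a tumour left out. At an unadjusted p under 0.05, limma gave 1079 lower and 1477 higher probes without centring and 212 higher in the table. Apart from the fewer samples when a tumour was left out, the cause was not tested.

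Correction for GC content and the mean over the probes of each gene were not run, because the files give no probe sequence or gene. The gene lists and antigen receptor loci have no values under any setting for the same reason. No paired analysis was possible because the 3 tumours form 1 group, and each ratio already sets a tumour against ear DNA of its own mouse. Median signal over local background was lowest in the ear channel of TL11, at 6.92. In the tumour channel of TL11, the one that a loss lowers, it was 9.42. How far background limits the depth of a loss was not tested.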

Other observations

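The tests of extra copies, of a strain difference, of both explanations at the 7 probes of chromosome 12, of loss of 1 copy on chromosome 19 and of probe length on each chromosome alone were chosen only after the result was seen. Outside the deep segments, 207 probe values lay at least 0.5 below their segment. TL11 had 31 such probes on chromosome 4 (2.52% of 1231), where TL8 had 5 and TL20 had 8, although the window of TL11 had a median of 0.02. TL20 had 22 on chromosome 19 (1.46% of 1510), where its window had a median of 0.15. Of the 31 probes of TL11, 3 were also low in TL8 and 4 in TL20. Differences between these counts were not tested.

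Low single probes in DNA that was otherwise lost may mark places where the parental strains differ in sequence and a tumour kept the parental copy that binds the probe poorly. Over all windows, low single probes recurred in a pair of tumours 48 times against 1.26 by chance, a ratio of 38.1. Their ear signal lay at a median of -1.05 from their neighbours on the log2 scale. A probe that reads low in any tumour would also give this. No tumour had a lost segment on chromosome 11. There, low probes recurred 2 times in TL11 and TL8, 6 times in TL11 and TL20 and 3 times in TL8 and TL20. The ratio therefore does not decide for a strain difference with loss of a parental copy. The ear signal of the low probes had a median percentile of 9.59, where a value below 5 had been set for weak ear signal as the cause. The bootstrap 95% interval of 6.37 to 13.3 treated all values as independent, although the same probes recurred between tumours. These probes were weak in ear all the same, so weak ear signal as the cause stays open. The 7 probes of chromosome 12 lay 0.83 above the lost flanks in TL8, which does not decide on a second deletion in TL11 and TL20, and that stays open. The ear signal there lay at -0.93 from neighbouring probes, and the value in TL8 was within 0.09 of its unlost DNA, as loss of opposite parental copies would give, but no genotype was measured and this stays a hypothesis.

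In all 3 tumours the densely tiled parts of chromosomes 11 and 16 stood above their flanks, by 0.18 on average on the log2 scale. Removing the trend on ear signal left a share of 0.972 of that height, and removing the trend on probe length left 0.683 (SD of 0.18 between the shares), which argues against either as the whole cause. By chromosome the share left without the length trend was 0.809 on chromosome 11 and 0.536 on chromosome 16, where the height in TL20 went from 0.14 to 0.05, so probe length stays open for chromosome 16. Extra copies shared by the tumours would have raised the height on chromosome 16 in TL8 by 0.11 over the mean of TL11 and TL20, and the difference was 0.00633 (SD of 0.04 between the heights of TL11 and TL20). GC content and any difference between tissues tied to position stay open, as untested. The densely tiled stretch of chromosome 12 was not part of these tests.

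In the deep segments of chromosome 19 in TL11 and TL8, the 146 probes had a median of -2.92 ± 1.01 (SD). The same probes were lost and not deep in the other of these 2 tumours, at -0.58, and the median difference was -2.36 ± 0.86 (SD), where loss of 1 of 2 copies in a pure sample allows no less than -0.42. The segments were selected at a median of -1.0 or lower, so a difference at or below -0.42 largely followed from that selection. It is therefore no separate test of loss of 1 copy. The measured depth of -2.92 lay below -1, the value that loss of 1 of 2 copies gives in a pure sample. The selection did not set how far below -1.0 the segments lay. Their medians were -3.19 ± 0.98 in TL11 and -2.82 ± 0.98 in TL8 (SD between probes), with 66 of 71 and 70 of 75 probes below -1. This depth argues against loss of 1 of 2 copies as the whole change in these 2 tumours. Loss of both copies is a candidate, and it was not tested. The ear signal of the 146 probes had a median percentile of 34.0 among all probes, so weak ear signal does not account for the depth.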
